A study of Mus musculus with 4 samples.

How the data were processed

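Liver RNA was measured on 4 Affymetrix Mouse Genome 430 2.0 arrays, 1 for each combination of genotype (wild-type or WHV/c-myc transgenic) and age (5 or 11 months). Per the labels, each array stands for 5 mice of the C57/BL6 strain. The labels speak both of mixed samples and of signals averaged over 5 samplings, so whether RNA was pooled before hybridisation or signals were averaged afterwards is not settled. Total RNA was extracted with Trizol and turned into biotin-labelled cRNA, per the labels' protocols.

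The deposited values were probe set intensities on a linear scale, as the values themselves show: they ran from 0 to 8783.5 over 45101 probe sets, with 0 missing. How the authors summarised probes into probe set intensities, corrected the background and scaled the arrays is not given in the sources used here. The log2 medians of the 4 arrays differed by 0.55, which was over the limit of 0.5 set before the data were examined, so the arrays were quantile normalized to a common distribution. The deposited scaling and a shift of each array to a common median served as alternatives.

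The median of all normalized values, an intensity of 28.275, served as a floor, and lower values were raised to it before log2 was taken. Gene names came from a platform annotation that listed 35890 of the 45101 probe sets, of which 34958 had 1 symbol and 932 had several; 34754 were matched by gene identifier to the RefSeq table of assembly GRCm38.p6, and 0 symbols needed updating. Probe sets with several symbols named no gene, and the 9211 unlisted probe sets are unnamed here. The array also carries 64 Affymetrix control probe sets. Each gene was represented by its single-symbol probe set with the highest mean log2 value. Of 18194 genes, 13949 were above the floor on at least 1 array and entered the comparisons. A gene below the floor on 1 array of a comparison has only a bound, written as at least that many fold, and a gene below it on both has no ratio.

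Ratios were taken for transgenic over wild-type at each age and for 11 over 5 months within each genotype. With 1 array per group there are no replicates, so no p-value, standard deviation or test is given, and the number of arrays limits the precision. Genes are called higher or lower at a 2-fold difference. A gene list is described by the median log2 ratio of its members, with genes below the floor on both arrays at 0, and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list of at least 5 measured genes stood apart when its median lay among the lowest or the highest 2.5% of random lists, as a description of these arrays. There were 32 gene lists and 13 lists of cell type markers, fixed before the data were examined. A few further lists were drawn up after the first results and before the values of their genes were looked at.

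Named genes followed a rule fixed at the same time: Myc, the 8 highest and 8 lowest ratios above the floor on both arrays whose other probe sets had the same sign, the 2 highest and 2 lowest bounds under the same rule of sign, and from each list up to 3 members with the largest ratios of at least 2-fold, or else the 1 member with the largest ratio. The rule further took the 5 genes per direction with the largest calls at both ages, the 3 per direction with the most opposed calls and the 5 highest and 5 lowest for each comparison between ages. Clone names were counted but not named.

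The alternatives were the other scalings, floors at the 25th and 75th percentiles, no floor with log2(value + 16), the mean of all probe sets of a gene, probe sets without the suffixes of multiple matches, size rules of 1.5-fold and 3-fold, the wild-type array of the other age or the mean of both as control, and random lists without matching. The steps were tested on simulated arrays that carried the spread of the wild-type pair, including any difference of age within that pair. The genes to change were drawn only from those well above the floor on both wild-type arrays, so recovery nearer the floor was not tested. Of 200 genes changed 4-fold, 98.5% were called at 5 months and 99% at 11 months, among 14041 simulated genes. In the same simulations 655 of 12619 unchanged genes at 5 months and 696 of 12647 at 11 months were also called at 2-fold. Of 200 genes changed 2-fold, which lies at the threshold, 45.5% and 51% were called among 14045. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.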

Results

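Expression was compared between livers of WHV/c-myc transgenic mice, which carry a c-myc transgene with woodchuck hepatitis virus sequences and develop liver tumours, and livers of wild-type mice of the same age. At 5 months the transgenic livers were free of tumours but dysplastic, a stage described as preneoplastic. At 11 months the transgenic sample was tumour tissue, mainly well-differentiated trabecular hepatocellular carcinoma, so that genotype and tumour tissue go together at that age. Each of the 4 groups had 1 array standing for 5 mice, without replicates. The deposited median intensities were 27.6 and 25.2 for the wild-type and transgenic arrays at 5 months, and 24.5 and 35.8 at 11 months. Between 11566 and 11772 genes per array lay above the floor. Myc itself was read by 1 probe set close to the floor, with log2 ratios of -0.59 at 5 months and -0.58 at 11 months that are bounds. Whether that probe set detects the transgene is not given in the sources used here, so it does not check the labels.

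The comparison at 5 months set dysplastic, tumour-free transgenic liver against wild-type liver. Ccnd1, which encodes the G1 cyclin D1, was 6.01-fold higher (log2 ratio 2.59), and Angptl8, a regulator of plasma triglycerides, was 4.29-fold higher. Cyp17a1, a steroid hydroxylase, was 4.11-fold higher, and Rps4l was 3.75-fold higher. Cyp17a1 is a member of the list of female-biased liver genes, which were high on this array, as given below. Igfbp1, an insulin-repressed binding protein of insulin-like growth factors, was 23.7-fold lower (log2 ratio -4.56). Bcl6, a transcriptional repressor, was 8.08-fold lower, and the immediate early gene Egr1 was 9.07-fold lower. The metallothioneins Mt1 and Mt2 were 4.45-fold and 4.95-fold lower, and the serum amyloid gene Saa1 was 4.62-fold lower. Atf3, a stress-induced transcription factor, was at least 3.60-fold lower, and Tubb4a was at least 3.49-fold lower.

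In all, 186 genes were higher and 171 lower at 5 months among 12639 with a ratio. As deposited, without normalization, the numbers were 137 higher and 208 lower. The total of 357 was below the 594 genes that differed 2-fold between the wild-type arrays of both ages. It was also below the mean of 680 calls on simulated arrays without a genotype difference that carried the spread of that wild-type pair. That spread may include differences of age, so the 680 may overstate calls made by noise alone. The 680 also lay above the 594 calls of the pair whose spread was simulated. Across probe sets the arrays at 5 months were closer to each other than that pair (Spearman's rho 0.905 against 0.877). Several of the leading genes differed between those wild-type arrays too. Igfbp1, Egr1, S100a8 and S100a9 had log2 ratios of -1.77, -2.04, -1.71 and -2.18 in wild-type liver at 11 over 5 months. Tubb4a lay at the floor in 11-month wild-type liver and so had no difference from that array, against which Atf3 was at -0.62 and S100a9 at -0.51. Rps4l, at 0.86, was also under 2-fold there. With the floor at the 75th percentile Atf3, Tubb4a and Rps4l stood at -0.41, -0.37 and 0.73. G0s2, an inhibitor of lipolysis, was 5.19-fold higher in transgenic liver at 5 months but 7.81-fold higher in wild-type liver at 11 than at 5 months, and its transgenic ratio turned to -0.59 against the 11-month wild-type array. Against that array, 93 of the 186 higher genes (50%) and 55 of the 171 lower genes (32.2%) were again 2-fold apart. Those simulated arrays gave 32.6% on average, because both ratios share the transgenic array. As they made more calls than the measured arrays, this share is only a rough yardstick for the comparison at 5 months.

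Most genes of ribosome production had ratios slightly above 0 at 5 months. The nucleolar and ribosome biogenesis list had a median log2 ratio of 0.24 (percentile 99.98), with 25 of 32 members above 0 and 0 at 2-fold; its largest ratio was that of Nop2, at 0.87. All 13 chaperonin and mitochondrial chaperone genes were above 0, with a median of 0.26 (percentile 99.92) and Cct3 at 0.69. Of 27 cytosolic ribosomal protein genes, 25 were above 0, with a median of 0.11 (percentile 99.21). The list of nucleotide, polyamine and one-carbon synthesis had a median of 0.19 (percentile 99.6), led by the serine synthesis gene Psph at 1.33, and did not stand apart with the floor at the 75th percentile (0.061, percentile 92.1). Psph was at 0.29 with that floor. The ribosomal protein list did not stand apart among random lists not matched on expression (percentile 97.1). The 40 proliferation genes did not stand apart, with a median of 0.00 (percentile 45.5) and 13 members below the floor on both arrays, although the replication licensing genes Mcm2 and Mcm4 reached 1.15 and 1.26. Without probe sets of multiple matches these ratios were 0.14 and 0.35.

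Lists of lipid synthesis genes stood apart with medians above 0 at 5 months. Of 20 cholesterol synthesis genes 18 were above 0, with a median of 0.54 (percentile 100); Sqle, the squalene epoxidase, reached 1.61, and Mvd 1.09. The fatty acid and triglyceride synthesis list had a median of 0.26 (percentile 99.99), with Aacs at 1.52, Elovl6 at 1.29 and Acacb, an acetyl-CoA carboxylase, at least 5.95-fold higher. Another probe set of Aacs had the opposite sign. The fatty acid oxidation list had a median of 0.23 (percentile 99.98), which turned to -0.17 against the 11-month wild-type array and to -0.0037 against the mean of both wild-type arrays. Cholesterol synthesis genes also had a low median of -0.60 (percentile 0) in wild-type liver at 11 over 5 months.

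Lists of clock, acute phase and hepatocyte enzyme genes stood apart with medians below 0 at 5 months. Lists also stood apart between the wild-type arrays, at 11 over 5 months. There the bile acid, amino acid and periportal lists were low (percentiles 0, 0.08 and 1.02) and the acute phase list was high (percentile 99.99). The circadian and complement lists did not stand apart there (percentiles 55.5 and 8.56). Standing apart can thus occur between arrays of the same genotype. The circadian list had a median of -0.39 (percentile 0.02), with Usp2 at -1.58, Per3 at -1.16 and Ciart at least 2.38-fold lower, and another probe set of Per3 had the opposite sign, with a mean of -0.19 over all its probe sets. With the floor at the 75th percentile the median was -0.14 and the list no longer stood apart (percentile 7.51). Ciart lay at the floor in 11-month wild-type liver and had no difference from that array. Of 28 acute phase genes 8 were 2-fold lower and 1 was higher, with a median of -0.14 (percentile 0.84), and Socs3, a feedback inhibitor of cytokine signalling, was at -1.47. With the mean of all probe sets the acute phase median was -0.096 and no longer stood apart (percentile 4.66), and without probe sets of multiple matches Socs3 was at -0.23. Complement and coagulation genes had a median of -0.15 (percentile 0.79) with 23 of 25 members below 0, and when arrays were shifted to a common median, which put the median of all genes at 0.068, the list lay at 0.00 and still stood apart low (percentile 0.55). The bile acid list had a median of -0.13 (percentile 2.41), which turned to 0.033 under that shift and no longer stood apart (percentile 5.46), nor did it as deposited, without probe sets of multiple matches or among unmatched random lists. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at -1.03. The amino acid catabolism list was at -0.17 (percentile 0.13) and the periportal list at -0.20 (percentile 0.81), with Etnppl at -1.08. Against the 11-month wild-type array neither stood apart, the periportal median turned to 0.067, and Cyp7a1 and Etnppl were at -0.53 and -0.46. The stellate cell, neutrophil, nucleotide and bile acid lists did not stand apart against that array either. Against the mean of both wild-type arrays the amino acid, periportal, bile acid and neutrophil lists did not stand apart.

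Genes of other cell types differed on the same array. Pancreatic acinar genes had a median of 2.26 (percentile 100), with 6 of 8 members at 2-fold; the elastase gene Cela2a was 9.61-fold higher, Cela3b at least 11.3-fold and the carboxypeptidase gene Cpb1 at least 5.27-fold. Female-biased liver genes had a median of 2.04 (percentile 100), with 10 of 15 at 2-fold, among them Sult2a2 at least 50.2-fold, Cyp3a44 at least 29.7-fold and Cyp2b9 at least 13-fold higher. Xist, which is transcribed from the inactive X chromosome of female cells, was 3.52-fold higher by a probe set above the floor on all 4 arrays. Another Xist probe set read 370 against 2.6, a log2 ratio of at least 3.71, and was above the floor on this array alone. The remaining one was below the floor on all 4 arrays. The Y-linked genes Eif2s3y and Uty had ratios of -0.18 and -0.29, and Kdm5d, named after its values were seen, had one of 0.41. Stellate cell and fibroblast markers had a median of 0.35 (percentile 99.96), with Col3a1 at 1.10, Dpt at 1.08 and Pdgfrb at 1.01. With the mean of all probe sets Col3a1 and Pdgfrb were at 0.61 and 0.50, and Dpt was at 0.80 against the 11-month wild-type array. The extracellular matrix list stood at 0.21 (percentile 99.53), and with the mean of all probe sets its median was 0.095 and no longer stood apart. Neutrophil and monocyte markers had a median of -0.43 (percentile 0.71), with S100a8 and S100a9 at -2.97 and -2.68.

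**Figure D1:**
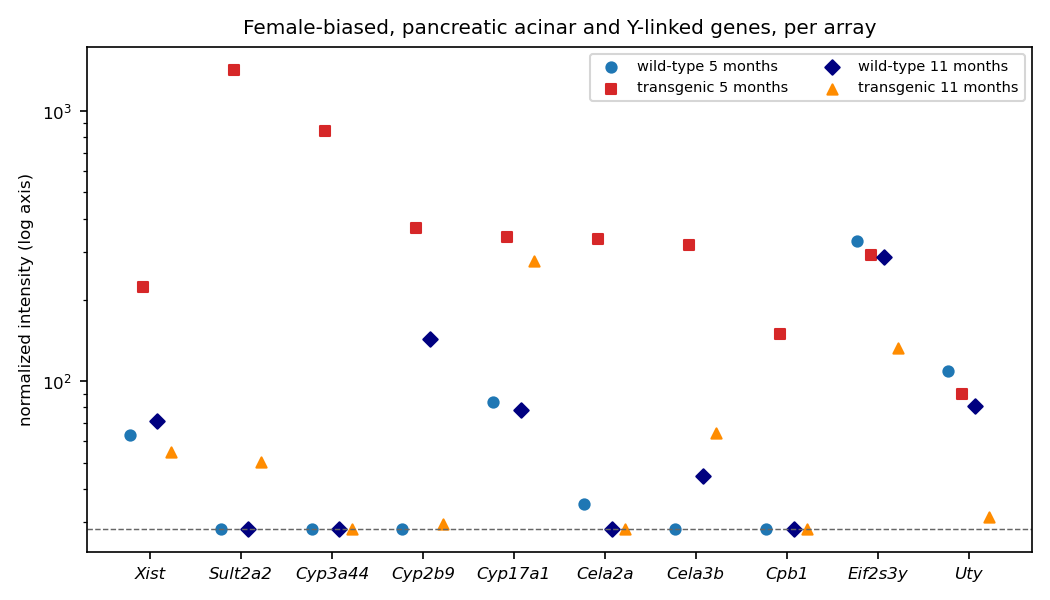
Normalized intensity (log axis) of female-biased, pancreatic acinar and Y-linked genes on each of the 4 arrays; each point is 1 array and the dashed line is the floor of 28.275. Sult2a2, Cyp3a44, Cela2a, Cela3b and Cpb1 were highest on the 5-month transgenic array, while Eif2s3y and Uty were lowest on the 11-month transgenic array.

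The comparison at 11 months set tumour tissue against wild-type liver. Igf2, a fetal growth factor, was 71.3-fold higher (log2 ratio 6.16), and Afp, the fetal serum protein used as a liver tumour marker, was at least 28.6-fold higher. Scd2, a stearoyl-CoA desaturase, was 22.3-fold higher, the fatty acid binding protein gene Fabp4 16-fold and the lipoprotein lipase gene Lpl 15.5-fold. Gsn, Aldh1b1 and Serpinb1a were 19.5-fold, 17.0-fold and 12.9-fold higher. The replication licensing genes Mcm4 and Mcm6 were 11.5-fold and at least 17.6-fold higher.

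Among the lowest genes at 11 months were several of mature hepatocytes. Of those named here, Slco1a1 and Hsd3b5 are members of the list of male-biased liver genes, which was low in tumours, as given below. Slco1a1, an organic anion transporter, was 29.3-fold lower and Sult2a8, a hepatic sulfotransferase, was 27.4-fold lower. Cyp1a2, a drug-metabolising cytochrome, was 21.8-fold lower, the carboxylesterase gene Ces1f 21.6-fold and the aminopeptidase gene Enpep 20.4-fold. Serpina12, the major urinary protein gene Mup10 and Rdh16f2 were 18.8-fold, 18.6-fold and 18.4-fold lower. Hsd3b5, a male-specific steroid dehydrogenase, was at least 34.5-fold lower, and Mfsd4b1 was at least 19.1-fold lower. In all, 1072 genes were higher and 839 lower among 12919 with a ratio, 14.8% against 2.82% at 5 months. As deposited, the numbers were 3062 higher and 244 lower, and the median of all genes lay at 0.51 on that scaling. Against the 5-month wild-type array, 749 of the 1072 higher genes (69.9%) and 521 of the 839 lower genes (62.1%) were again 2-fold apart.

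Lists of growth genes stood apart with medians above 0 in the tumours. All 40 proliferation genes were above 0 and 33 were 2-fold higher, with a median of 2.35 (percentile 100); Ect2, required for cytokinesis, was at least 11.8-fold higher. Of 32 nucleolar and ribosome biogenesis genes 24 were 2-fold higher, with a median of 1.44 (percentile 100), led by Nop56 at 2.61, Nhp2 at 2.27 and Ncl at 1.98. The nucleotide, polyamine and one-carbon list had a median of 1.16 (percentile 100), with the serine synthesis gene Psat1 at least 14.8-fold higher and Ctps and Srm at 2.74 and 2.27. All 27 ribosomal protein genes and all 13 chaperone genes were above 0, with medians of 0.84 and 0.88 (percentile 100 for both). The oncofetal list had a median of 0.54 (percentile 99.94), with Tff3 at 2.79.

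Glycolysis genes had a median of 0.72 (percentile 99.93), with Pkm at 2.46 and Hk2, a hexokinase low in adult hepatocytes, at 1.26. The glycolysis median was 0.28 with the floor at the 75th percentile and no longer stood apart (percentile 97.1), and Hk2 was at 0.44. The oxidative phosphorylation list stood at 0.31 (percentile 99.95), with 1 of 28 members, Atp5o, at 2-fold, and Atp5o was at 0.76 against the 5-month wild-type array. Of 16 p53 target genes 6 were 2-fold higher, with a median of 0.86 (percentile 99.99); Cdkn1a, the cell cycle inhibitor p21, was at least 9.20-fold higher. The p53 list did not stand apart against the 5-month wild-type array, where its median was 0.30, or with the floor at the 75th percentile, where it was 0.31. Asns, the asparagine synthetase of the ATF4 response, was at 3.45, although its list did not stand apart (median 0.19, percentile 94.0).

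Several lists of hepatocyte functions stood apart with medians below 0 in the tumours. All 17 pericentral genes were below 0 and 12 were 2-fold lower, with a median of -1.24 (percentile 0), among them Oat at -4.00 and the glutamate transporter gene Slc1a2 at -3.96. The periportal list stood at -0.70 (percentile 0.3), with Pck1 at -2.77 and Igf1 at -2.31 but Aldh1b1 at 4.09, and with the floor at the 75th percentile its median was -0.47 and no longer stood apart (percentile 3.18). Of 23 cytochrome P450 genes 11 were 2-fold lower and 2 higher, with a median of -0.92 (percentile 0); Cyp2a12 was at -3.86 and Cyp2c54 at -3.47. Bile acid genes had a median of -0.83 (percentile 0.02), with Cyp7b1 at -2.74. Complement and coagulation genes stood at -0.64 (percentile 0.29), with the lectin gene Mbl1 at -3.48, C8a at -3.32 and C6 at -3.06. Amino acid catabolism genes stood at -0.56 (percentile 0.81), with Agxt at -2.12, and without probe sets of multiple matches their median was -0.46 and no longer stood apart (percentile 5.25). The hepatocyte marker list itself did not stand apart (median -0.59, percentile 5.47), nor did secreted plasma proteins (-0.41, percentile 15.9). Fatty acid oxidation, gluconeogenesis and glutathione genes did not stand apart either, with medians of -0.36, -0.26 and -0.17 that were 0.055, 0.20 and 0.48 as deposited, each below the median of 0.51 of all genes on that scaling.

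Male-biased liver genes were the lowest list in tumours, with 12 of 17 at 2-fold and a median of -2.34 (percentile 0), including Elovl3 at -3.59. Slco1a1, Hsd3b5, Cyp7b1 and C6, named above, belong to this list too, so it overlaps with the bile acid and complement lists. Female-biased genes did not stand apart (median 0.00, percentile 59.7). The Y-linked genes Eif2s3y and Uty were 2.17-fold and 2.57-fold lower, while Kdm5d was at 0.32. As deposited, Eif2s3y and Uty were less than 2-fold lower, at 173 against 239.3 and 39.9 against 67.2, as they were with the mean of all probe sets, with log2 ratios of -0.56 and -0.78. Xist had a ratio of -0.37 and was above its wild-type value as deposited, at 70.9 against 59.4. Its probe set that was above the floor only on the 5-month transgenic array was below the floor here, at 5.3 against 1.6 as deposited. The circadian list stood at -1.06 (percentile 0), with Dbp, an output gene of the clock, at -3.61 and Arntl, the gene of the clock activator BMAL1, at 1.77, where another probe set of Arntl had the opposite sign and its ratio was 0.77 against the 5-month wild-type array.

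Markers of macrophages and of stellate cells differed in direction within their lists in the tumours. The Kupffer cell lectin gene Clec4f was at -2.75, while the macrophage gene Gpnmb was at least 7.77-fold higher and Lgals3 was 7.58-fold higher. Among 16 endothelial genes 4 were 2-fold lower, 0 were higher and 6 were above 0, with the sinusoidal genes Clec4g and Fcgr2b at -2.82 and -1.71, and the list did not stand apart (median -0.27, percentile 6.0, and 0.27 as deposited against 0.51 for all genes). The stellate cell gene Lrat, needed for vitamin A storage, was at least 4.50-fold lower and Ecm1 was at -2.18, while the collagen gene Col3a1 was at 2.89. Lrat was at -0.73 with the floor at the 75th percentile, and Fcgr2b at -0.89 with the mean of all probe sets. The extracellular matrix list stood apart at 0.42 (percentile 99.62), with the collagen gene Col4a1 at 2.76. MHC class II genes had a median of 0.94 (percentile 99.95), with H2-Aa at 1.23 and Cd74 at 1.15; against the mean of both wild-type arrays the median was 0.47 and no longer stood apart, and H2-Aa and Cd74 were at 0.62 and 0.61 against the 5-month array. Skeletal muscle genes had a median of -0.87 (percentile 0.02), with 2 of 7 members 2-fold lower. These members, Ckm and Atp2a1, were at -0.46 and -0.78 against the 5-month wild-type array. In wild-type liver at 11 over 5 months the muscle list had a median of 0.23 and did not stand apart (percentile 89.6).

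**Figure D2:**
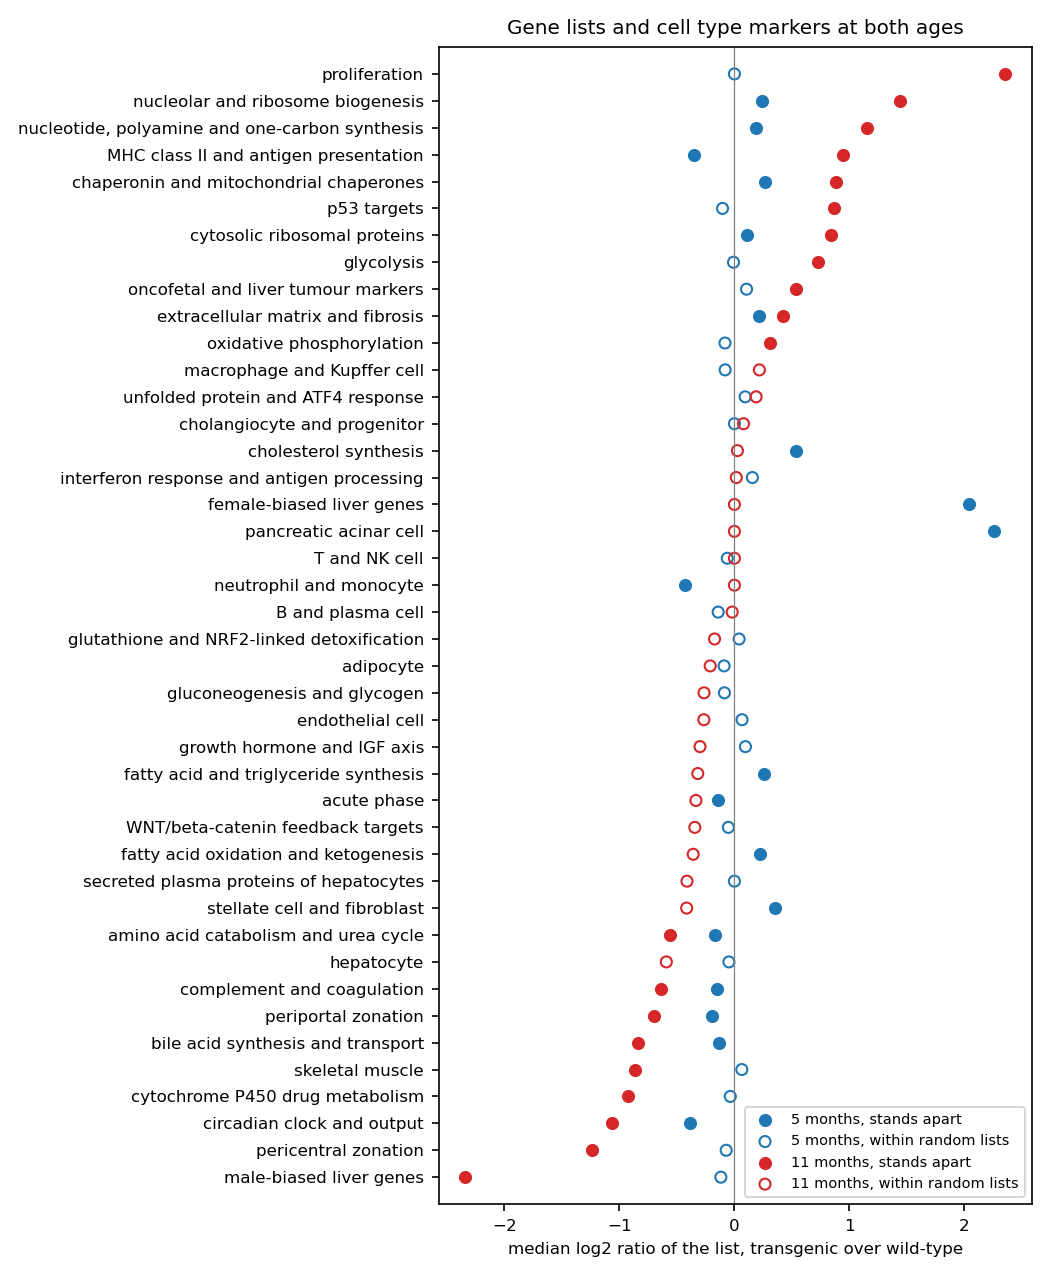
Median log2 ratio of each gene list and cell type marker list, transgenic over wild-type, at 5 months (blue) and 11 months (red). Filled points lie among the lowest or highest 2.5% of 10000 random lists and open points lie between them. Proliferation genes stood at 0.00 and 2.35, and male-biased genes at -0.12 and -2.34.

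Both ages shared a small part of their differences. Nol12, Rps4l, Cyp17a1, Ccnd1 and Emp2 were higher at both ages, and Bcl6, Saa1, Plk3, Usp2 and Socs3 were lower at both. At 11 months Ccnd1 was 3.28-fold and Cyp17a1 3.55-fold higher, and Bcl6 was 5.11-fold lower. Cyp17a1 belongs to the female-biased list, which stood apart at 5 months but not at 11 months. Another probe set of Emp2 had the opposite sign at 5 months. Against the wild-type array of the other age, Rps4l was at 0.86 at 5 months and Saa1 at -0.51 at 11 months, both under 2-fold. Without probe sets of multiple matches Socs3 was at -0.23 and -0.55. Nol12, Emp2 and Plk3 were under 2-fold at 5 months with the floor at the 75th percentile, at 0.85, 0.27 and -0.18, and Plk3 was at -0.51 at 11 months. Of 11609 genes with a ratio at both ages, 48 were higher in both and 32 lower in both, where independent lists would share 13.6 and 10.9. Opposite calls numbered 13 for higher then lower and 20 for lower then higher, where independent lists would give 11.9 and 12.4. Across the 9473 genes above the floor on all 4 arrays the log2 ratios had Pearson's r of 0.21 and Spearman's rho of 0.22, and genes are not independent replicates. The correlation was 0.079 when each transgenic array was set against the wild-type array of the other age. A difference of age common to both genotypes then enters the ratios with opposite signs and would lower their correlation. The 0.079 is therefore no check of the 0.21.

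**Figure D3:**
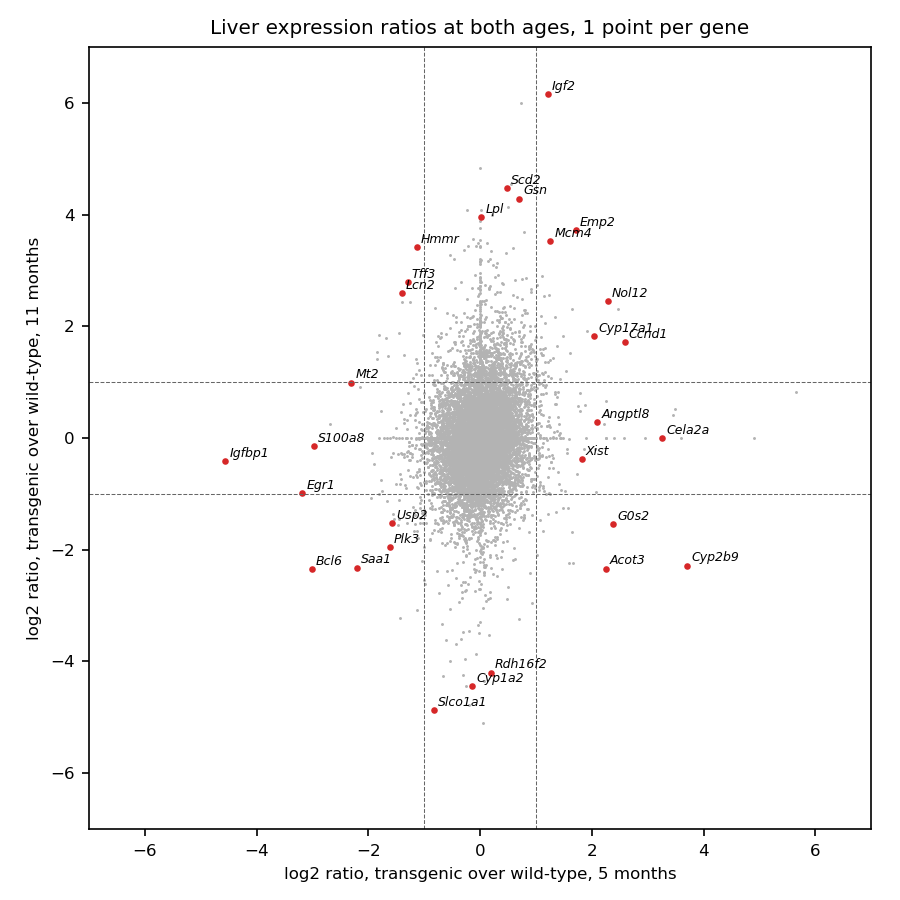
Log2 ratio of transgenic over wild-type at 5 months (horizontal axis) against 11 months (vertical axis), 1 point per gene, with dashed lines at the 2-fold limits and named examples in red. Igf2 lies at 1.21 and 6.16, and Bcl6 at -3.01 and -2.35. At 5 months Igf2 was at 0.60 with the mean of all probe sets and 0.86 against the 11-month wild-type array. With the floor at the 75th percentile it had no difference at that age.

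With age, wild-type liver differed by 275 higher and 319 lower genes among 12809, or 117 and 456 as deposited, where the median of all genes lay at -0.15. Saa2 was 9.48-fold higher at 11 months, G0s2 7.81-fold, Gnai1 4.46-fold, the acyl-CoA thioesterase gene Acot3 4.31-fold and Trpc4ap 3.83-fold. With the floor at the 75th percentile Gnai1 and Trpc4ap were at 0.86 and 0.63, and Trpc4ap was at 0.97 with the mean of all probe sets. Lsm7 was 5.15-fold lower, S100a9 4.52-fold, Pdzd11 4.50-fold, Egr1 4.11-fold and the flap endonuclease gene Fen1 3.99-fold. Without probe sets of multiple matches Pdzd11 was at -0.010 and Fen1 at 0. With the mean of all probe sets they were at -0.73 and -0.998, both under 2-fold. Acute phase genes had a median of 0.21 (percentile 99.99) and bile acid genes one of -0.31 (percentile 0).

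Between the transgenic arrays, tumours at 11 months against tumour-free liver at 5 months, 884 genes were higher and 765 lower among 13015, or 2474 and 359 as deposited, where the median of all genes lay at 0.43. Igf2 was 39.4-fold higher, the iron-binding lipocalin gene Lcn2 21.5-fold, Scd2 16.9-fold, Zfas1 16.7-fold and Serpinb1a 14.3-fold. Cyp1a2 was 32.6-fold lower, Sult2a2 28.4-fold, the fatty acid elongase gene Elovl3 27.7-fold, Rdh16f2 24.1-fold and Sult2a8 22.4-fold. Sult2a2, a female-biased gene, lay at the floor on both wild-type arrays. In tumours its log2 ratio over wild-type was at least 0.82. Between the transgenic arrays female-biased genes had a median of -1.99 and pancreatic acinar genes one of -2.26 (percentile 0 for both). Both lists were high on the 5-month transgenic array. Proliferation genes had a median of 2.06 (percentile 100) and cholesterol synthesis genes one of -1.06 (percentile 0).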

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

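The tests of Xist with the second female-biased list, of the Y-linked genes, of the first acinar list at 11 months and of the hybridisation controls were chosen after the result was seen, while the second acinar list and the share of signal in the brightest probe sets were set before.

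Female-biased liver genes and Xist were higher on the 5-month transgenic array. A female-like programme in livers of males is argued against by Xist, whose probe sets above the floor had a median log2 ratio of 2.76, where the stronger of them is a bound. A whole pool of females or a swapped female array is argued against by Eif2s3y, Kdm5d and Uty, whose median ratio was -0.18. Some female mice in the pool are a candidate explanation. A second list of 11 measured female-biased genes had a median of 0.32 (percentile 98.68), with 2 members at 2-fold, 7 above 0 and 4 below. The labels give no sex, so female mice in the pool stay a hypothesis, and an effect of the transgene on these genes stays open.

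Pancreatic acinar genes were higher on the same array, with normalized intensities of 337 for Cela2a and 319 for Cela3b, and 5 of 8 members below the floor in wild-type liver. Pancreatic tissue in the pool is a candidate explanation: a second list of 14 measured acinar genes had a median of 0.28 at percentile 99.72, although its member Reg1, chosen here after its value was seen, stayed below the floor. Acinar genes switched on in liver cells by the transgene cannot be told apart from this. The first list had a median of 0.00 at 11 months, with 4 of 8 members below the floor on both arrays, which met the bound of 0.5 set for ruling that explanation out. The bound was wrong by design, since the 11-month array holds tumour tissue and expression in tumour-free liver alone stays open.

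The 11-month transgenic array was brighter over all genes as deposited. A brighter scan or a higher scaling factor is argued against by the hybridisation controls, whose median log2 ratio was 0.12 against 0.51 for all genes, unless the scaling offset a different amount of control. The 200 probe sets brightest in wild-type liver held 11.3% of the signal on that array and at least 15.6% on the others, which is consistent with less signal in the most abundant liver transcripts. How the authors scaled the arrays is not given in the sources used here.

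Some ratios took opposite directions at 5 and 11 months, and these differences were not tested, as each group has 1 array. Cyp2b9, Acot3 and G0s2 were higher and then lower, with log2 ratios that differed by -5.99, -4.58 and -3.92 (11 minus 5 months). These genes also differed between the wild-type arrays, with ratios of at least 2.35 for Cyp2b9, 2.11 for Acot3 and 2.97 for G0s2 at 11 over 5 months. Against the wild-type array of the other age, Cyp2b9 stood at 0.062 at 11 months, Acot3 at 0.14 and -0.23 at 5 and 11 months, and G0s2 at -0.59 and 1.42, so none of the 3 kept opposite 2-fold calls. Hmmr, Tff3 and Lcn2 were lower and then higher, with differences of 4.55, 4.08 and 4.01. Against the wild-type array of the other age, Hmmr turned to 0.23 at 5 months and Tff3 was at -0.50, while Lcn2 stood at -1.83 and 3.02. With the floor at the 75th percentile the 5-month ratios of Hmmr, Tff3 and Lcn2 were 0, -0.36 and -0.41. MHC class II genes stood apart in opposite directions, with a median difference of 1.26. Their 5-month median turned to 0.25 against the 11-month wild-type array, and did not stand apart against the mean of both wild-type arrays (-0.032), with the mean of all probe sets (-0.17) or without probe sets of multiple matches (-0.29). The wild-type arrays themselves differed by -0.54 in these genes (percentile 0.11).

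Outside the gene measurements, the poly-A control transcripts had a median log2 ratio of 0.94 for the 5-month transgenic over wild-type array as deposited, with 24 of 24 probe sets higher. It was -1.32 between the transgenic arrays (0 of 24 higher), -0.44 between the wild-type arrays (4 of 24) and 0.13 at 11 months (15 of 24). The 3-prime to 5-prime ratio of the transferrin receptor control was 0.57 on the 11-month wild-type array and 2.44 to 2.69 on the others. That of actin ran from 1.63 to 2.32 and that of Gapdh from 0.79 to 0.86.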

How the results depend on the processing

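All alternatives were set before the data were examined, except the count without sex-biased and acinar list genes, which was chosen after. Of 1992 values of named genes under the alternatives, 1792 kept their side of the 2-fold limit. A change of sign met 13 of these values, 6 with a 2-fold call under either setting and 7 without one, all against another wild-type control. Of 828 list medians, 751 kept their side of the percentile limits. Counts followed the floor and the size rule by construction, and list percentiles without matching followed the draw. The cause of the other shifts was not tested. Without the genes of the sex-biased and acinar lists, 163 genes were higher and 171 lower at 5 months, and 1067 and 822 at 11 months. Genes near the floor give only bounds, which limits what these arrays can show for weakly expressed genes. A model of genotype plus age over all 4 arrays, which would pair the genotypes by age, was not run. Its only residual would be the difference between the transgenic over wild-type ratios of the 2 ages. Against the mean of both wild-type arrays the ratios of both ages share their denominator, which by construction raises their correlation and lowers the number of opposed calls. There the correlation was 0.34 and the covariance 0.098, where simulated unchanged arrays gave 0.34 and 0.053, and opposed calls averaged 0.30 on those. As deposited the median of all genes lay at 0.51 at 11 months, so a list could stand apart low with a median at or above 0.

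With the floor at the 25th percentile, genes numbered 968 higher and 915 lower (5 months), 1901 higher and 1666 lower (11 months), 1251 higher and 1223 lower (wild-type age) and 1833 higher and 1712 lower (transgenic age). There, shared calls numbered 331 and opposed calls numbered 251. There, interferon at 5 months (0.21) newly stood apart high. There, WNT feedback at 11 months (-0.87) and male-biased liver genes at 5 months (-0.25) newly stood apart low. With the floor at the 75th percentile, genes numbered 54 higher and 45 lower (5 months), 574 higher and 491 lower (11 months), 42 higher and 71 lower (wild-type age) and 427 higher and 418 lower (transgenic age). There, shared calls numbered 33 and opposed calls numbered 8. There, nucleotide synthesis at 5 months (0.061), glycolysis at 11 months (0.28), periportal zonation at 11 months (-0.47), p53 targets at 11 months (0.31) and circadian at 5 months (-0.14) no longer stood apart. There, macrophage at 11 months (0.45) and interferon at 5 months (0.12) newly stood apart high. There, pericentral zonation at 5 months (-0.17) newly stood apart low. Without a floor, on log2(value + 16), genes numbered 322 higher and 293 lower (5 months) and 485 higher and 501 lower (wild-type age). There, cholangiocyte at 5 months (0.31) and interferon at 5 months (0.22) newly stood apart high. There, WNT feedback at 11 months (-0.40) and male-biased liver genes at 5 months (-0.23) newly stood apart low. With the mean of all probe sets, genes numbered 116 higher and 96 lower (5 months), 703 higher (11 months), 165 higher and 161 lower (wild-type age) and 560 higher (transgenic age). There, shared calls numbered 40 and opposed calls numbered 21. There, acute phase at 5 months (-0.096), MHC class II at 5 months (-0.17) and extracellular matrix at 5 months (0.095) no longer stood apart. There, unfolded protein at 11 months (0.18) newly stood apart high. There, endothelial cell at 11 months (-0.29), adipocyte at 5 months (-0.26), pericentral zonation at 5 months (-0.15) and male-biased liver genes at 5 months (-0.25) newly stood apart low. At 1.5-fold, genes numbered 925 higher and 910 lower (5 months), 2426 higher and 2347 lower (11 months), 1221 higher and 1194 lower (wild-type age) and 2276 higher and 2091 lower (transgenic age). At 3-fold, genes numbered 39 higher and 27 lower (5 months), 352 higher and 215 lower (11 months), 31 higher and 42 lower (wild-type age) and 253 higher and 226 lower (transgenic age). Against the wild-type array of the other age, genes numbered 343 higher and 297 lower (5 months). There, the correlation between ages was 0.079 and opposed calls numbered 80, where differences of age common to both genotypes enter with opposite signs. There, stellate cell at 5 months (0.18), neutrophil at 5 months (-0.26), nucleotide synthesis at 5 months (0.15), bile acid at 5 months (-0.025), amino acid catabolism at 5 months (-0.0081) and p53 targets at 11 months (0.30) no longer stood apart. There, cholangiocyte at 5 months (0.37), oncofetal at 5 months (0.24), interferon at 5 months (0.31), unfolded protein at 5 months (0.31) and growth hormone at 5 months (0.29) newly stood apart high. There, stellate cell at 11 months (-0.42), neutrophil at 11 months (-0.61), adipocyte at 11 months (-0.70) and growth hormone at 11 months (-1.24) newly stood apart low. There, G0s2 at 5 months (-0.59), Cdh1 at 11 months (-0.078), Saa2 at 11 months (0.017), Cyp2b9 at 11 months (0.062), G0s2 at 11 months (1.42), Hmmr at 5 months (0.23), fatty acid oxidation at 5 months (-0.17), periportal zonation at 5 months (0.067) and MHC class II at 5 months (0.25) changed sign. Against the mean of both wild-type arrays, genes numbered 104 lower (5 months). There, the correlation between ages was 0.34 and opposed calls numbered 13. There, neutrophil at 5 months (-0.31), bile acid at 5 months (-0.034), amino acid catabolism at 5 months (-0.088), periportal zonation at 5 months (-0.041), MHC class II at 5 months (-0.032) and MHC class II at 11 months (0.47) no longer stood apart. There, cholangiocyte at 5 months (0.25), interferon at 5 months (0.24) and unfolded protein at 5 months (0.18) newly stood apart high. There, growth hormone at 11 months (-0.77) newly stood apart low. There, fatty acid oxidation at 5 months (-0.0037) changed sign. As deposited, genes numbered 3062 higher and 244 lower (11 months), 117 higher (wild-type age) and 2474 higher and 359 lower (transgenic age). There, bile acid at 5 months (-0.098) no longer stood apart. There, stellate cell at 11 months (0.10), pancreatic acinar cell at 11 months (0.00), acute phase at 11 months (-0.030) and female-biased liver genes at 11 months (0.00) newly stood apart low. With unmatched random lists, cytosolic ribosomal proteins at 5 months (0.11) and bile acid at 5 months (-0.13) no longer stood apart. There, interferon at 5 months (0.16) newly stood apart high. There, hepatocyte at 11 months (-0.59), stellate cell at 11 months (-0.42), plasma protein at 11 months (-0.41), fatty acid oxidation at 11 months (-0.36), lipid synthesis at 11 months (-0.32) and acute phase at 11 months (-0.33) newly stood apart low. Without probe sets of multiple matches, bile acid at 5 months (-0.11), amino acid catabolism at 11 months (-0.46) and MHC class II at 5 months (-0.29) no longer stood apart. There, endothelial cell at 11 months (-0.38), B and plasma cell at 5 months (-0.36), WNT feedback at 11 months (-0.34) and male-biased liver genes at 5 months (-0.17) newly stood apart low. With arrays shifted to a common median, WNT feedback at 11 months (-0.32) and acute phase at 11 months (-0.58) newly stood apart low. There, complement at 5 months (0.00050) and bile acid at 5 months (0.033) changed sign.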

Other observations

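Of 15 genes of the growth hormone and IGF axis, 5 were 2-fold lower and 1 was higher in tumours, with 7 above 0 and 8 below. The list did not stand apart, with a median of -0.30 (percentile 16.3), or 0.36 as deposited, where the median of all genes was 0.51. Igf1 was at -2.31, Egfr at -2.43 and Lifr at -2.67, and another probe set of Egfr had the opposite sign. Egfr is also a member of the male-biased list. The WNT feedback list had a median of -0.34 in tumours (percentile 2.64), or 0.14 as deposited and so again below that of all genes, with Lect2 at -3.53 and Notum at -1.54 but Ccnd1 at 1.71. Of the acute phase genes, Saa2 was 9.37-fold lower in tumours than in wild-type liver at 11 months but had a log2 ratio of 0.017 against the 5-month wild-type array, and Lcn2 was 6.07-fold higher.

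In tumours Tfrc, which encodes the transferrin receptor, had a ratio of 2.86 and the heme synthesis gene Alas2 one of -2.64. T and NK cell markers did not stand apart (median 0.00, percentile 48.3), with Ccl5 at least 3.38-fold higher. B and plasma cell markers did not stand apart either (median -0.02, percentile 42.0, and 0.50 against 0.51 for all genes as deposited), with Jchain at -1.08. Under the alternatives Jchain was at -0.42 as deposited, -0.66 with the floor at the 75th percentile, -0.90 without a floor and -0.97 under the common median. At 5 months Jchain was at -1.96, or -0.88 against the 11-month wild-type array. Of 4 measured genes of a pancreatic islet list drawn up after the first results, 0 were 2-fold higher at 5 months and their median was 0.23.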
